A study of Mus musculus with 9 samples.

How the data were processed

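Lung RNA of 9 mice was read on single-colour (Cy3) Agilent mouse miRNA arrays, 1 array per mouse, with 3 mice in each of 3 groups. Per the labels, the groups are control, with no treatment named, model, with D-galactose and sodium nitrite and 42 days, and codonopsis, with Codonopsis pilosula at 15 g per kg and 30 days. The labels of the codonopsis arrays do not say whether those mice also received D-galactose and sodium nitrite, although the title of the series calls the plant an intervention in ageing mice. Per the labels, control 1, codonopsis 1 and codonopsis 2 came from male mice and the other 6 arrays from female mice.

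Per the file headers, the scanner files hold linear fluorescence intensity written by Agilent Feature Extraction version 11.5.1.1, while the submitters' notes name version 10.10. The deposited processed intensity is corrected for background and for spatial trends within the array, can be negative, and is not scaled between arrays. The deposited detection call of each miRNA is a flag of 0 or 1, and the deposited total intensity of a miRNA is 0.1 wherever that flag is 0. The deposited value table of the series holds log2 values. Its columns shared 1 maximum and followed the log2 total intensity of their own array with r from 0.9944 to 0.9991, and it holds 0.000001 where a miRNA was not detected, so the authors appear from the values to have quantile-normalised detected miRNAs. That table and the total intensity were used as alternatives only.

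The arrays carry 1881 mouse miRNAs on 4415 probes and 56430 spots, with 7 to 30 spots per probe and 1 to 4 probes per miRNA, beside 2164 control spots. Spots marked as non-uniform or as outliers by Feature Extraction were left out, which were 3.05% of spots, except where all spots of a probe were marked. The processed intensity was averaged over the spots of a probe and then over the probes of a miRNA. Each array was divided by its 75th percentile over the 289 miRNAs detected on all arrays, values under 0.00391 were set to that floor (log2 −8), and log2 was taken. Printed levels are these log2 scaled signals, and printed differences are differences of their group means with the standard error (SE) of the fit. The 404 miRNAs detected on all 3 arrays of at least 1 group were tested. A further 246 were detected on some array but not tested, and 1231 were detected on none. Where no array of a group detected a miRNA, its fold is a lower bound: the mean log2 signal of the other group against the mean, over the arrays of this group, of the higher of the lowest signal of any detected miRNA on that array and the miRNA's own signal. Where the miRNA's own signal is the higher on each of these arrays, this equals the fitted fold. The fitted value is then given and is no bound.

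One limma model (version 3.58.1 in R 4.3.3) was fitted to all 9 arrays with group as its factor, which leaves 6 residual degrees of freedom. Moderated tests (lmFit and eBayes, two-sided) gave model minus control, codonopsis minus model and codonopsis minus control, and a moderated F test asked for any difference among the 3 groups. Male minus female was estimated in a second fit with group as a covariate. P-values were adjusted with the Benjamini-Hochberg method over the 404 miRNAs, with a threshold of 0.05. They measure the spread between these mice, and the number of arrays limits the precision. In 20 simulated sets per comparison, built with the variances of these arrays and 80 changed miRNAs, the fit found 59.4% to 63.1% of changes of 1 on the log2 scale and 84.5% to 86.4% of changes of 2, with 3.64% to 4.12% of its calls false. The simulated miRNAs varied independently and no simulated array stood apart, unlike the real arrays. These shares therefore need not hold for the real comparisons.

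For 23 lists of miRNAs, limma's camera tested whether a list moved relative to the other miRNAs, with a preset correlation of 0.01 and adjustment over the 21 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move 1 way on balance, and its mixed form whether they change in either direction. The lists were miR-34 family, senescence and ageing, inflammation, hypoxia, NRF2 regulation and oxidative stress, miRNAs known to rise and miRNAs known to fall in fibrotic lung, let-7 family, miR-30 family, miR-17 to miR-92 clusters, the cluster of miR-183, miR-96 and miR-182, the Dlk1-Dio3 imprinted cluster, X-linked miRNAs, GC-rich or rRNA-matching entries, and markers of lung epithelium, multiciliated cells, endothelium, smooth muscle and fibroblasts, heart and striated muscle, erythroid cells, myeloid cells and leukocytes, lymphocytes and other organs. Reversal was measured as the covariance over miRNAs of model minus control with codonopsis minus model. Since both share the model arrays, it was set beside 1000 simulated sets with no group effect and the same variances, one-sided. In these sets the miRNAs varied independently, so their range is narrower than that of correlated miRNAs.

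The groups, tests, lists and rule for naming miRNAs, and all but 2 of the alternatives, were fixed before the data were examined. The rule names, per comparison and direction, up to 10 miRNAs past the threshold with the largest change. It fills each direction to 10 with the smallest unadjusted p among miRNAs whose 3 arrays of 1 group all lie above or all below the 3 of the other, and these are given as values. It also names the 2 to 4 members of a described list with the smallest p and the 5 smallest p of the sex comparison. Other names are among the brightest miRNAs, cell type markers read by array, and miRNAs of fits without 1 array, chosen after their values were seen.

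Alternatives were other scalings (75th percentile over all miRNAs, quantile normalization, median), other signals (total intensity, the deposited log2 table, normexp background correction with an offset of 50), other probe summaries, floors and detection filters. Others were sex as a covariate, female mice, each comparison fitted with its own 2 groups, a trended and robust prior, array quality weights, another threshold, other list tests, and leaving out each array. Normexp used the median intensity of each spot because the mean named in the plan is not a column of these files. The offset of 50 exceeds the signal of dim miRNAs and shrinks their differences, so small normexp values cannot decide their direction. After seeing the data, slide row as a covariate and a fit without miR-297, miR-466, miR-467 and miR-669 entries were added. All control arrays lay in row 1 and all model arrays in row 2. The row term therefore rests on codonopsis 3 against codonopsis 1 and 2. With it, codonopsis vs control is the fit without codonopsis 3, and codonopsis vs model sets codonopsis 3 alone against the model arrays. Slide as a block was not run, because the control arrays are alone on their slide and the other 2 groups share theirs. Scan date was not run because it follows the slide. No position in the genome is given, because no genome of the build named in the headers was used here. Files were read with data.table version 1.17.8, and figures were drawn with matplotlib 3.10.9 from Python 3.11.15.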

Results

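The miRNA content of lung tissue was measured on 9 arrays, 3 each for control mice, mice given D-galactose and sodium nitrite (model), a treatment used to imitate ageing, and mice given Codonopsis pilosula (codonopsis), a plant of traditional Chinese medicine. Between 375 and 484 of the 1881 miRNAs were detected per array. The 75th percentile of signal lay between 244.54 and 538.24. The net signal of the negative control spots was 24.024 to 28.432, a measure unlike the background-corrected intensity used for miRNAs. The brightest miRNAs included miR-126a-3p, an endothelial miRNA, at 5.47 ± 0.27 (SD, n = 3) in control, 5.86 ± 0.0655 (n = 3) in model and 5.66 ± 0.243 (n = 3) in codonopsis lungs. The erythroid miR-451a stood at 4.95 ± 0.16, 4.93 ± 0.358 and 5.08 ± 0.442 in the same order.

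All 3 control arrays lay on slide 2 and the other 6 on slide 1, so slide and group cannot be told apart in comparisons with control, whereas codonopsis and model share a slide. Control 1 stood apart. Its median correlation with the other arrays was 0.886, against 0.951 to 0.978 for the rest, and 10 miRNAs made up 63.51% of its signal, against 53.25% to 57.6% elsewhere. Sex was unequal, with no male model mouse, 1 male control (control 1) and 2 male codonopsis mice. On slide 1 the male arrays lay in row 1 and the female arrays in row 2, so sex and row coincide there.

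**Figure D1:**
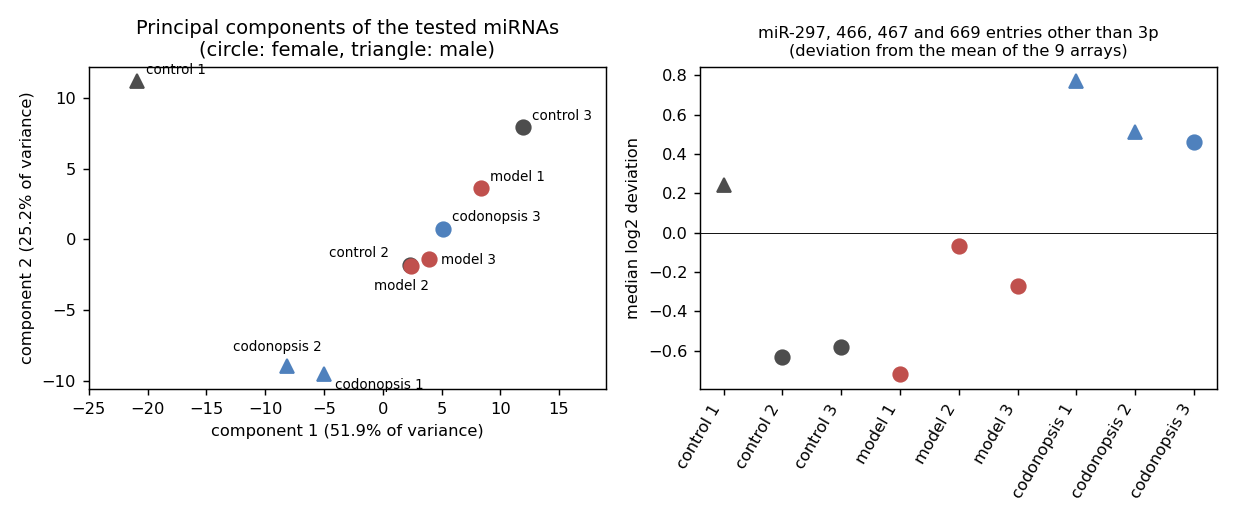
Left, the 9 arrays on the first 2 principal components of the 404 tested miRNAs (no unit), in which component 1 holds 51.9% of the variance and places control 1 at −20.9. Right, the median log2 deviation of 22 miR-297, miR-466, miR-467 and miR-669 entries from their 9-array mean, from 0.46 to 0.77 on the codonopsis arrays and from −0.72 to −0.07 on the model arrays.

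The comparison of model with control asks which miRNAs differed in lung after D-galactose and sodium nitrite. Members of the let-7 family, abundant miRNAs known to restrain growth-promoting genes, were higher on the model arrays. For let-7b-5p the level was 4.29 ± 0.069 (SD, n = 3) in model and 3.90 ± 0.0422 (n = 3) in control lungs, a log2 difference of 0.38 (SE 0.11), with every model array above every control array. For let-7i-5p the levels were 3.50 ± 0.0559 (n = 3) and 3.10 ± 0.121 (n = 3), a difference of 0.39 (SE 0.14). All 9 tested members of the let-7 list were higher, by 0.10 to 0.39 with a median of 0.29. Under quantile normalization, however, their median of 0.11 lay below the median of 0.36 over all tested miRNAs, and the direction relative to other miRNAs turned. The dim let-7k, tested but not on the list, was lower at −0.21 (SE 0.373). The let-7 list rose in the camera test (adjusted p = 0.0014) but not with an estimated correlation (adjusted p = 0.99) or by fry (adjusted p = 0.298).

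Senescence and ageing miRNAs and those known to fall in fibrotic lung rose with D-galactose and sodium nitrite in the camera test, but not with an estimated correlation (adjusted p = 0.99 for both). Of 17 tested senescence and ageing miRNAs, 16 were higher, with a median of 0.22 (camera adjusted p = 0.0281), but not with an estimated correlation (adjusted p = 0.99) or by fry (adjusted p = 0.51). Among them were miR-128-3p at 0.70 (SE 0.256) and miR-146b-5p, an inhibitor of inflammatory signalling, at 0.38 (SE 0.177). Unlike the fibrosis miRNAs, this list was not split by known direction, so its rise does not point towards or away from ageing. Of 12 miRNAs known to fall in fibrotic lung, 11 were higher, with a median of 0.26 (camera adjusted p = 0.0374, 0.99 with an estimated correlation, 0.51 by fry), a direction that turned relative to other miRNAs under quantile normalization. Its members included miR-200c-3p, known to keep cells epithelial, at 0.47 (SE 0.131), and miR-30d-5p at 0.36 (SE 0.137), while miR-326-3p was lower at −0.38 (SE 0.175). These lists share 4 members with each other, and the fibrosis list shares let-7d-5p with the let-7 family. No member of the 3 lists passed over all miRNAs or adjusted over the list alone, where the smallest values were 0.08 for let-7, 0.41 for senescence and ageing and 0.0938 for fibrosis.

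Outside these lists, miR-195a-5p, a relative of miR-15 and miR-16, was higher in model lungs at 2.85 ± 0.0993 (n = 3) against 2.13 ± 0.331 (n = 3). Other named miRNAs with model values above every control array were miR-29b-1-5p at 0.74 (SE 0.177), miR-6360 at 0.57 (SE 0.134), miR-466f-5p at 0.92 (SE 0.229), miR-200a-5p at 0.80 (SE 0.23), detected on 2 control arrays, and the X-linked miR-361-5p at 0.41 (SE 0.117). Detected on every model array and on no control array, miR-135a-1-3p was at least 1.71-fold and miR-466a-5p at least 1.83-fold higher. With normexp both had the opposite sign (−0.10 and −0.07), as did miR-466f-5p (−0.04), beside a median of −0.07 over all tested miRNAs. Among miRNAs lower than every control array was miR-126a-5p, the partner strand of the endothelial miR-126a-3p, at −0.89 (SE 0.218), and it alone passed adjusted over the list alone in the endothelium list of 2 (adjusted p = 0.00753). Over all miRNAs its limma adjusted p was 0.283, and the other member, the brighter miR-126a-3p, went the other way at 0.39 (SE 0.184). Others named by the rule were miR-186-5p at −0.74 (SE 0.157), miR-1904 at −0.69 (SE 0.207), miR-149-5p at −1 (SE 0.319, detected on 1 model array), miR-700-3p at −0.80 (SE 0.256, detected on 2 control arrays), miR-1198-5p at −0.53 (SE 0.17) and miR-5622-3p at −0.54 (SE 0.209). Differences of −0.44 for miR-1231-5p, and of −0.44 for miR-6997-5p and −0.39 for miR-7222-3p, both detected on 2 control arrays, completed those named.

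No miRNA passed in limma for model against control (smallest adjusted p 0.283), with 47 at an unadjusted p under 0.05, 35 of them higher, where chance gives 20.2. The 3 model arrays lay all above the 3 controls for 58 miRNAs and all below for 36, 23.3% of those tested, against 10% by chance. Both chance values are averages, and since miRNAs vary together a single comparison can lie far from them. Only 1 list passed without model 1. Without control 1 no list passed, and the let-7 median was 0.20, that of senescence and ageing 0.07 and that of fibrosis 0.11. Other scalings moved the median of all miRNAs from 0.04 to between 0.18 and 0.60, under which miR-1198-5p, miR-1231-5p, miR-5622-3p, miR-6997-5p and miR-7222-3p had the opposite sign in at least 1 of them, and with the deposited log2 table miR-186-5p (0.09) and miR-700-3p (0.15) did so too.

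**Figure D2:**
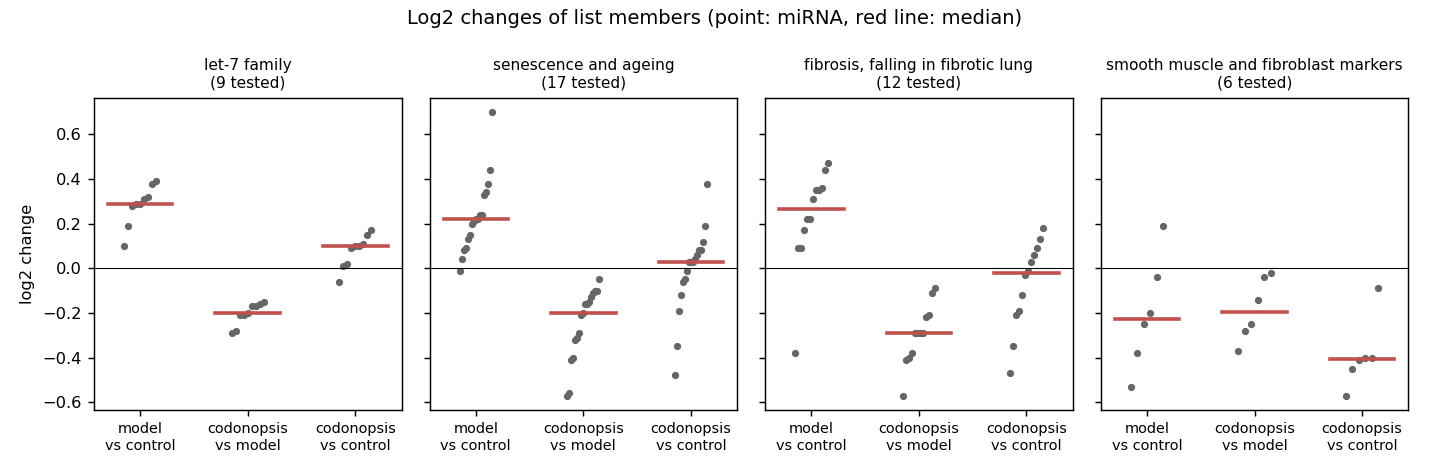
Log2 changes of the tested members of 4 lists (points) with the median (line) in each comparison. The let-7 medians are 0.29 for model vs control and −0.20 for codonopsis vs model, directions that turned relative to other miRNAs under quantile normalization for the first and with the deposited log2 table for the second, and the smooth muscle and fibroblast median is −0.40 for codonopsis vs control.

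The comparison of codonopsis with model asks what differed after the plant, on arrays of 1 slide. On the codonopsis arrays miR-574-5p, whose sequence repeats U and G, stood above every model array, at 0.74 ± 0.228 (n = 3) against −0.05 ± 0.17 (n = 3) in model lungs, a difference of 0.79 (SE 0.173). For miR-1187 the levels were −0.41 ± 0.155 and −1.41 ± 0.242, and for miR-3082-5p they were 0.08 ± 0.135 and −0.89 ± 0.219. From the Sfmbt2 gene cluster, miR-466c-5p differed by 1.01 (SE 0.259) and miR-466f-5p by 0.83 (SE 0.229). Chosen after its values were seen, the set of 22 tested miR-297, miR-466, miR-467 and miR-669 entries other than 3p arms was higher for 21, with a median of 0.96, and the median stayed above 0 under every scaling and signal, from 0.22 with normexp to 1.15 with the brightest probe. Of the 8 tested 3p entries of these families 4 were higher, with a median of 0.09.

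Also above every model array were miR-670-5p at 1.25 (SE 0.301, detected on 1 model array), miR-3097-5p at 1.13 (SE 0.275, detected on 1 model array) and miR-99b-3p at 0.68 (SE 0.183, detected on 2 model arrays), which was −0.02 with normexp and −0.06 with the deposited log2 table. No model array detected miR-1306-3p or miR-5709-3p. Their fitted differences were 1.24 (SE 0.276, 2.36-fold) and 1.09 (SE 0.299, 2.12-fold), and as low as 0.02 and 0.04 among the alternatives. Lower on every codonopsis array were miR-21a-5p, a miRNA raised in inflamed and fibrotic lung, at 2.54 ± 0.0817 (n = 3) against 3.10 ± 0.195 (n = 3), and miR-29b-1-5p at −5.78 ± 0.0499 against −4.92 ± 0.282, a difference of −0.86 (SE 0.177). Others named by the rule were miR-6538 at −0.81 (SE 0.179), miR-3960 at −0.68 (SE 0.158), miR-3102-5p at −0.64 (SE 0.195) and miR-3081-5p at −0.86 (SE 0.263). Smaller differences were −0.38 for miR-6931-5p, −0.41 for miR-30a-3p, −0.37 for miR-214-3p, made by mesenchymal cells, and −0.32 for miR-7a-1-3p.

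The 3 lists that rose in the model comparison fell here in the camera test, but not with an estimated correlation (adjusted p = 0.774 for all 3). All 12 miRNAs known to fall in fibrotic lung were lower, with a median of −0.29 (adjusted p = 0.0166), among them miR-29b-3p, which represses collagen genes, at −0.57 (SE 0.259) and miR-200c-3p at −0.29 (SE 0.131). All 17 senescence and ageing miRNAs were lower, with a median of −0.20 (adjusted p = 0.0415), miR-21a-5p and miR-29b-3p among them. All 9 let-7 members on the list were lower, with a median of −0.20 (camera adjusted p = 0.0415), a direction that turned relative to other miRNAs with the deposited log2 table. The dim let-7k, tested but not on the list, was higher at 0.97 (SE 0.373). Fry gave an adjusted p of 0.351 for the fibrosis and let-7 lists and 0.389 for senescence and ageing. Sex was unequal between these groups, and no list passed in camera with sex as a covariate. Slide row as a covariate, chosen after the result was seen, leaves codonopsis 3 alone against the model arrays and cannot decide this. The median of all tested miRNAs was −0.11, and it lay between −0.47 and −0.07 under the other scalings. No member of these lists passed over all miRNAs or adjusted over the list alone, where the smallest values were 0.185 for fibrosis, 0.421 for senescence and ageing and 0.261 for let-7. Among GC-rich or rRNA-matching entries, 2 of 9 passed adjusted over the list alone, with miR-3960 lower and miR-1187, itself rich in U and G, higher, and the mixed form of fry gave that list an adjusted p of 0.00325.

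No miRNA passed in limma for codonopsis against model in the fit of all 9 arrays (smallest adjusted p 0.189), with 43 at an unadjusted p under 0.05, of which 20 were also at least 2-fold higher and none at least 2-fold lower. The groups did not overlap for 150 of 404 miRNAs (60 above, 90 below), 37.1% against an average of 10% by chance. Since miRNAs vary together, a single comparison can lie far from that average, so this share is no test. Without control 1, whose spread enters the pooled variance, 35 passed, 32 of them higher, and in a fit of the 6 arrays of slide 1 alone 17 passed, 14 of them higher and all 17 among the 35. Among the 35 are some miRNAs that read far higher on control 1 than on the other controls, such as miR-7058-3p and miR-8114. For the miRNAs that set control 1 apart, codonopsis minus model had a median of 0.65. Over all tested miRNAs the excess of control 1 over controls 2 and 3 correlated with codonopsis minus model at r = 0.44. The 35 can therefore not be taken as separate from what sets control 1 apart. Of the 3 lists none passed without model 1 or without codonopsis 2, 1 passed without codonopsis 3, and 2 lists passed on slide 1 alone. Those 17 miRNAs include miR-1187, miR-3082-5p, miR-466c-5p and miR-1306-3p above the model level and miR-6538, miR-29b-1-5p and miR-3960 below it.

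**Figure D3:**
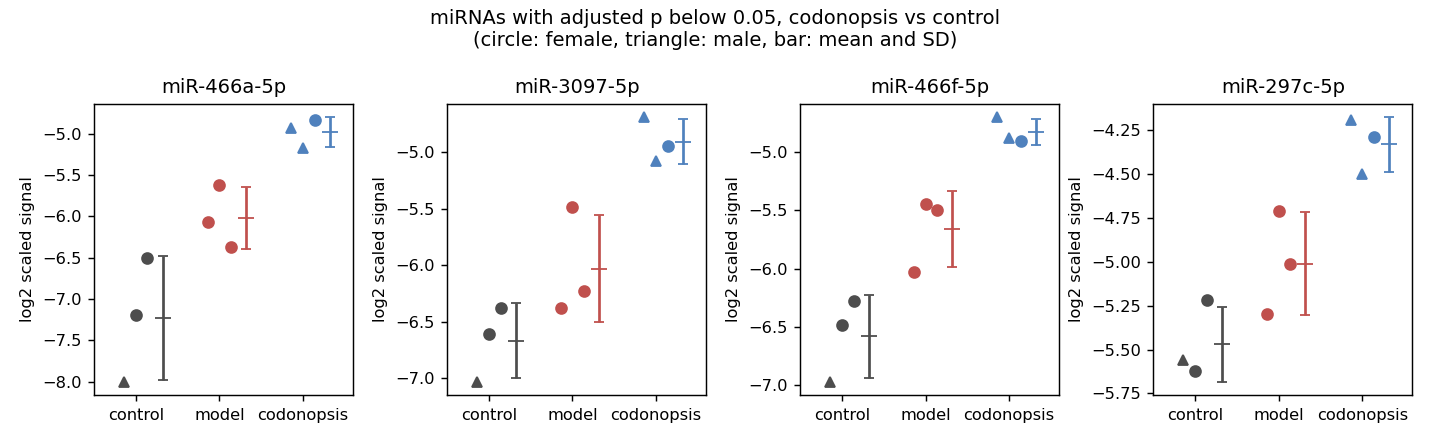
Log2 scaled signal of the 4 miRNAs past the threshold for codonopsis vs control, each array as a point (triangles male, circles female), with the mean and SD of 3 arrays per group. For miR-466f-5p the codonopsis mean is −4.83 and the control mean −6.58.

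The comparison of codonopsis with control asks how codonopsis lungs differed from control lungs, and here 4 miRNAs rose and none fell. From the Sfmbt2 cluster, miR-466f-5p rose by 1.75 (SE 0.229, adjusted p = 0.0306), from −6.58 ± 0.356 (n = 3) to −4.83 ± 0.113 (n = 3), and miR-297c-5p by 1.14 (SE 0.193, adjusted p = 0.0426), detected on 2 control arrays. No control array detected miR-466a-5p, which rose at least 3.75-fold, or miR-3097-5p, which rose at least 3.36-fold (adjusted p = 0.0426 for both). In each case all 3 codonopsis arrays lay above all 3 controls. The mean processed signals of these 4 were 14 to 22 on the codonopsis arrays and 2.89 to 9.25 on the controls. The median over detected miRNAs lay between 26.417 and 35.984 per array. Since the filter counts detection per group, miR-466a-5p and miR-3097-5p were tested only because arrays of treated groups detected them. With a filter for detection on at least 1 array, or with no filter, no miRNA passed in this comparison. With normexp the differences were −0.01 for miR-466a-5p and 0.00 for miR-3097-5p, beside a median of −0.11 over all tested miRNAs, and none of the 4 passed there. None of them passed with the 75th percentile over all miRNAs, with quantile normalization or with the deposited log2 table, where 3 others passed. With slide row as a covariate, chosen after the result was seen, none of the 4 and 2 others passed. That fit is here the same as leaving out codonopsis 3, since only codonopsis arrays lie in both rows.

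Other named miRNAs above every control array were miR-670-5p at 1.62 (SE 0.301, 3.08-fold, detected on no control array), miR-466p-5p at 2.13 (SE 0.404, detected on 1 control array), miR-466c-5p at 1.25 (SE 0.259), miR-574-5p at 0.83 (SE 0.173), miR-99b-3p at 0.86 (SE 0.183, detected on 1 control array) and miR-6360 at 0.59 (SE 0.134). With normexp miR-670-5p (−0.08) and miR-99b-3p (−0.17) had the opposite sign, beside a median of −0.11 over all tested miRNAs. The endothelial miR-126a-5p stood at −3.16 ± 0.416 (n = 3) against −2.17 ± 0.174 (n = 3), a difference of −0.99 (SE 0.218), and passed adjusted over the list alone in the endothelium list (adjusted p = 0.00427). Over all miRNAs its limma adjusted p was 0.0783, and its partner strand miR-126a-3p was higher by 0.19 (SE 0.184). Also lower were miR-186-5p at −0.76 (SE 0.157), miR-3960 at −0.58 (SE 0.158), miR-1231-5p at −0.54 (SE 0.16), miR-6516-3p at −0.51 (SE 0.16), miR-149-5p at −0.99 (SE 0.319, detected on 1 codonopsis array) and miR-6898-5p at −0.87 (SE 0.284). The bright miR-3963 was at 4.94 ± 0.162 against 6.41 ± 0.914, with 7.42 on control 1. Further values were −1.15 (SE 0.344) for miR-5128 and −0.72 (SE 0.236, 1.64-fold lower) for miR-6970-5p, detected on no codonopsis array and on 2 control arrays.

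Smooth muscle and fibroblast markers fell against control in the camera test, with all 6 tested members lower and a median of −0.40 (adjusted p = 0.0343), but not with an estimated correlation (adjusted p = 0.95) or by fry (adjusted p = 0.23). Among them, miR-145a-5p of smooth muscle differed by −0.57 (SE 0.258), miR-143-5p by −0.40 (SE 0.17), and the mesenchymal miR-199a-5p and miR-214-3p by −0.45 (SE 0.154) and −0.41 (SE 0.146). None passed over all miRNAs or adjusted over the list alone, where the smallest value was 0.0717. Among the GC-rich or rRNA-matching entries, 3 of 9 passed adjusted over the list alone, miR-3960 and miR-3963 lower and miR-1187 higher, and the mixed form of fry gave an adjusted p of 0.00573. In limma 58 miRNAs had an unadjusted p under 0.05, 29 in each direction, and the codonopsis arrays lay all above the controls for 23 miRNAs and all below for 28, 12.6% against 10% by chance. Without control 1, 46 passed, the 4 included, 7 of them lower, among these miR-142a-3p of leukocytes at −1.39 and miR-126a-5p at −1.09, and the smooth muscle list did not pass. The 46 also include miRNAs that read far higher on control 1 than on the other controls, such as miR-8114. Without codonopsis 1, control 2 or model 3, no miRNA passed, and of the 4 miRNAs only miR-466f-5p passed without codonopsis 2 and none without codonopsis 3. Without codonopsis 1, codonopsis 3 or control 2 the smooth muscle list did not pass either.

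In the test of any difference among the 3 groups, 0 of 404 miRNAs passed (smallest adjusted p 0.104), with 54 at an unadjusted p under 0.05, and 36 passed without control 1. Across miRNAs, 66.8% had opposite signs in model minus control and codonopsis minus model, against a mean of 66.6% (62.1% to 71.5%) in simulated arrays with no group effect, with let-7b-5p and miR-29b-1-5p higher in the model and lower after codonopsis. The covariance of both differences was −0.0998, and simulated arrays with no group effect gave a mean of −0.121, from −0.192 to −0.067. Values as negative arose in 739 of 1000 simulated sets. Without control 3 the covariance was more negative than in all simulated sets, with a difference of −0.111 from their mean.

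**Figure D4:**
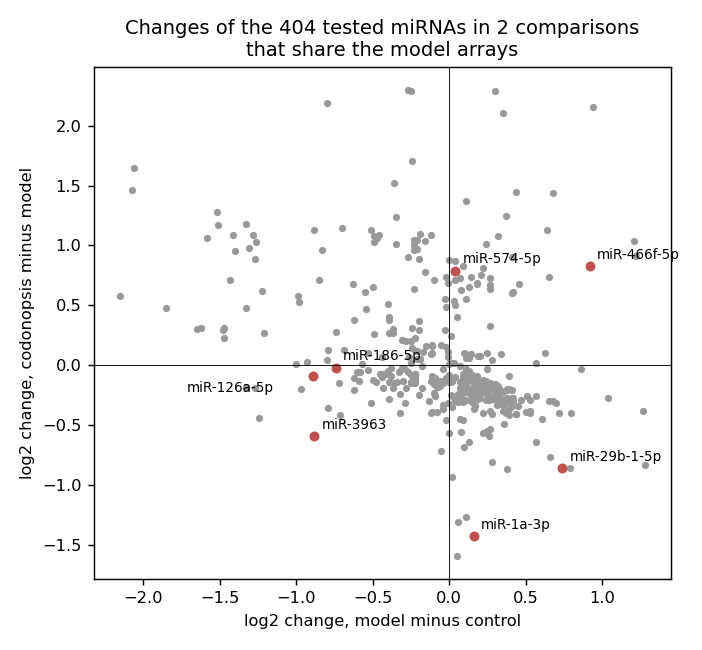
Log2 change codonopsis minus model against log2 change model minus control for 404 miRNAs (points), 7 of them named. Both axes use the model arrays with opposite sign, and 66.8% of points have opposite signs, against a mean of 66.6% in simulated arrays with no group effect.

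Male minus female differences, with group as a covariate, asked whether sex altered lung miRNAs. The smallest p belonged to let-7k at 1.04 (SE 0.135, adjusted p = 0.0503), which was negative under 3 other scalings or signals (−0.24 to −0.05). Next came miR-6980-5p at 1.88 (SE 0.284), miR-3070-2-3p at 1.68 (SE 0.281), miR-466f-3p at 4.26 (SE 0.727), which was 2.53 without control 1, and miR-669e-5p at 1.42 (SE 0.247), each with an adjusted p of 0.051. In limma 0 of 404 passed, with 111 at an unadjusted p under 0.05, 80 of them higher in males. Control 1 is the 1 male of its group and no male is in the model group, so these values rest on controls and codonopsis mice, and counts without single arrays are given in the closing part. Scaling by the 75th percentile over all miRNAs gave 254, most of them lower in males, beside a median of −1.17 over all miRNAs, and quantile normalization gave 149 beside a median of −0.56.

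**Figure D5:**
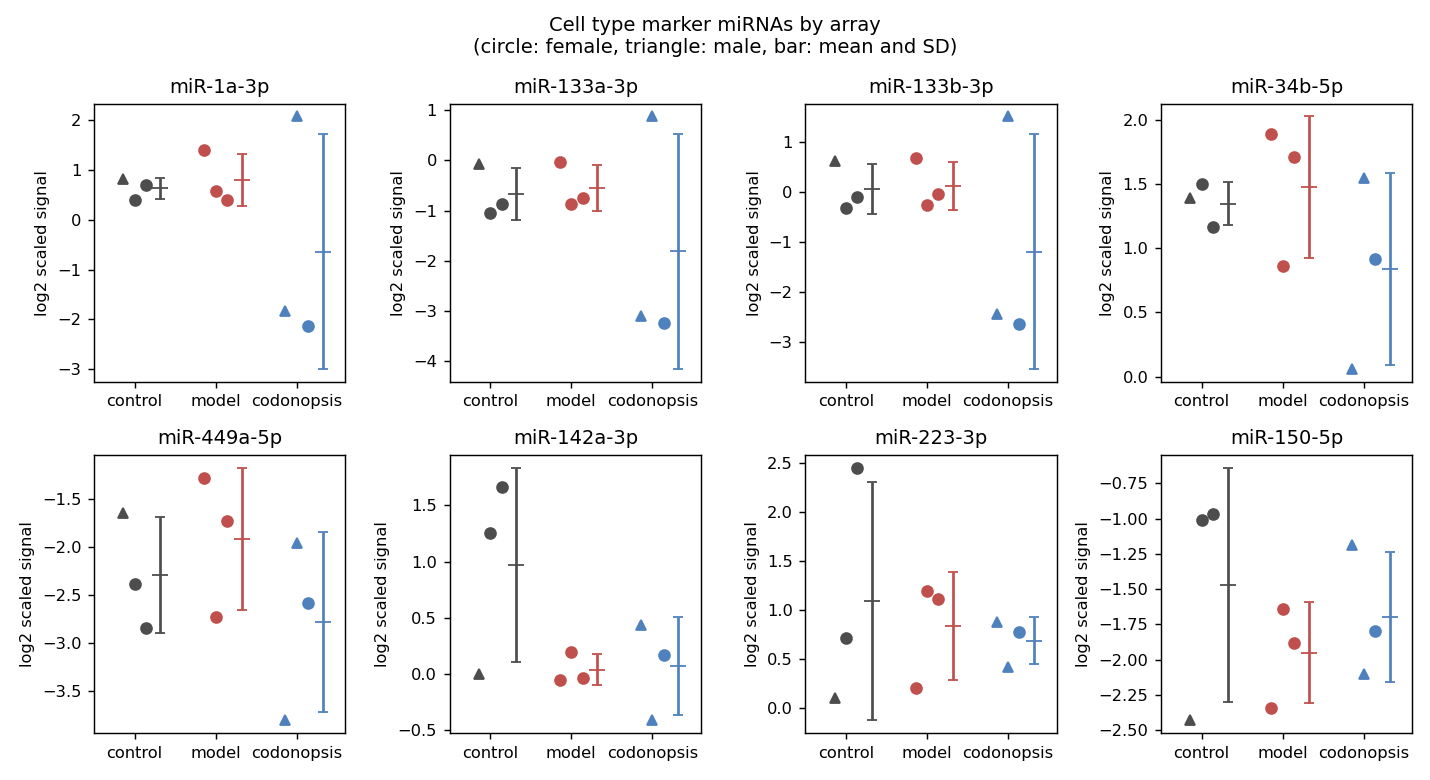
Log2 scaled signal of 8 marker miRNAs on each array (triangles male, circles female) with the mean and SD of 3 arrays per group. For miR-1a-3p the codonopsis arrays read −1.84, 2.07 and −2.14, and the control and model arrays 0.40 to 1.39.

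Among markers of cell types, lung epithelium miRNAs (10 tested) had medians of 0.15 for model minus control, −0.25 for codonopsis minus model and −0.05 for codonopsis minus control, the order used for all medians here. Multiciliated cell markers (5 tested) had 0.13, −0.57 and −0.51, heart and striated muscle markers (5) 0.11, −1.27 and −1.15, and erythroid markers (4) 0.00, 0.12 and 0.18. Myeloid and leukocyte markers (5) had −0.18, −0.15 and −0.18, and lymphocyte markers (5) 0.04, −0.03 and −0.06. Endothelium markers (2) had −0.25, −0.15 and −0.40 and markers of other organs (2) 0.22, −0.21 and 0.01, both too few for the list test. The endothelium markers moved in opposite directions in both comparisons with control. Smooth muscle and fibroblast markers had −0.23 and −0.20 in the first comparisons.

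Among processes and families, inflammation (8 tested) had medians of 0.12, −0.18 and −0.04, hypoxia (8) 0.23, −0.21 and 0.07, and NRF2 regulation and oxidative stress (9) 0.09, −0.13 and −0.04. The miR-34 family (5), which p53 induces, had 0.13, −0.53 and −0.51, but its miR-34b and miR-34c members are also multiciliated markers, miR-34a-5p differed by −0.13 from the model, and the median deviation was −1.17 on codonopsis 1 against 0.32 and −0.28 on codonopsis 2 and 3. The miR-30 family (7) had 0.14, −0.29 and −0.07, and the miR-17 to miR-92 clusters (10) 0.11, −0.19 and −0.02. The cluster of miR-183, miR-96 and miR-182 (3) had 0.13, −0.23 and −0.10, the Dlk1-Dio3 imprinted cluster (8) −0.06, −0.13 and −0.24, and X-linked miRNAs (23) 0.18, −0.23 and 0.02. The miRNAs known to rise in fibrotic lung (9) had 0.08, −0.25 and −0.33, and GC-rich or rRNA-matching entries (9) 0.10, −0.34 and −0.03. The lists that passed had, in their remaining comparisons, 0.10 for let-7, 0.03 for senescence and ageing and −0.02 for miRNAs known to fall in fibrotic lung, each for codonopsis minus control.

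None of these 3 or of the other lists passed in the comparisons of the preceding medians, where the smallest adjusted p was 0.0647 for X-linked miRNAs in model against control, 0.0561 for the miR-30 family and for lung epithelium in codonopsis against model, and 0.317 for miRNAs known to rise in fibrotic lung in codonopsis against control. Median, mean and test differed in sign in model against control for the miR-34 family, multiciliated and lymphocyte markers (median above 0, mean below 0, test down), for GC-rich entries (mean −0.01, test up) and for miRNAs known to rise in fibrotic lung (mean 0.00, test down). They also differed for lymphocyte markers in both comparisons of codonopsis (medians −0.03 and −0.06, test up) and for senescence and ageing in codonopsis against control (mean −0.01, test up). Apart from the entries named, no member of any list passed over all miRNAs or adjusted over the list alone.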

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

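The interaction test and the tests of control 1 were chosen only after the result was seen.

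In a limma interaction test of sex with codonopsis minus control, 62 of 404 miRNAs passed, 15 of them with a higher difference in males, with 123 at an unadjusted p under 0.05. The male control arm is control 1 alone and the female codonopsis arm is codonopsis 3 alone, and 31 of the 62 are among the 32 miRNAs that set control 1 apart, so the test cannot be read as a difference between sexes. The smallest adjusted p was 0.00112 for miR-669f-3p, which read −0.24 on the 1 male control array and −4.71 as the mean of the female controls, against −4.59 and −4.88 on the male and female codonopsis arrays. In the other direction, miR-598-3p read −6.52 and −6.08 on male and female controls and −2.47 and −5.97 on male and female codonopsis arrays. The fit had 4 residual degrees of freedom, and the model group has no male for the same test.

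Of the 246 miRNAs detected on some array but not tested, 25 were detected on at least 2 of 3 codonopsis arrays and on no control array, while 5 were detected on at least 2 of 3 control arrays and on no codonopsis array. Of the 25, 24 were detected on both male codonopsis arrays and 1 on the female one, and none reached 2 of 3 model arrays. For miR-302c-5p the codonopsis arrays read −5.21, −4.97 and −8, the last at the floor and the female one.

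Control 1 read more than 2 on the log2 scale above the higher of controls 2 and 3 for 32 miRNAs, with a median excess over the mean of controls 2 and 3 of 4.08 (2.42 to 7.38), and 24 of them are 3p arms and 10 are miR-466, miR-467 or miR-669 entries. Sex as the whole cause is argued against by the same 32 miRNAs in codonopsis mice, where male minus female had a median of 0.53 (MAD 0.45). For fragments of ribosomal RNA, the GC-rich or rRNA-matching entries were higher on control 1 by a median of 0.46 (MAD 0.41, −0.04 to 1.51), with a limit written after the value was seen. The set of 32 was chosen for its excess and this list was not, so their difference cannot decide on such fragments. The low signal of this array and its scaling as the whole cause are argued against by the 0.98 that scaling moves control 1 by, against the 4.08 (MAD 0.87) of the set. This test was written after its values were seen and replaced the median of −0.06 over the other miRNAs, which scaling fixes, and the unscaled excess of 3.10, whose sign the choice of the set fixes. A part played by sex, since control 1 is the 1 male control, and a difference in the RNA or labelling of this sample also stay open and were not tested.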

How the results depend on the processing

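Slide row as a covariate and the fit without miR-297, miR-466, miR-467 and miR-669 entries were chosen only after the result was seen, and the other alternatives were planned. The slide row term rests on codonopsis 3 against codonopsis 1 and 2. Its codonopsis vs control fit is that without codonopsis 3, no separate check, and its codonopsis vs model fit sets codonopsis 3 alone against the model arrays.

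Of 266 counts and reversal values under the alternatives, 149 kept their direction and side of the threshold or stayed within 1.5 times, 60 were weaker, 52 stronger and 5 turned, and of 2040 values of named miRNAs and lists 1743 stayed, 150 were weaker, 114 stronger and 33 turned. Unless said otherwise the cause was not tested. Counts of miRNAs are against 4 in codonopsis vs control and 0 in each other comparison, and counts of lists against 3 in model vs control, 3 in codonopsis vs model and 1 in codonopsis vs control.

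Lists passed in no comparison (0, 0 and 0) with the 75th percentile over all miRNAs, quantile normalization, the deposited log2 table, female mice, slide row as a covariate, fry, or camera with an estimated correlation. In the order model vs control, codonopsis vs model and codonopsis vs control, lists passed as 7, 9 and 0 for miRNAs detected on at least 1 array and 9, 14 and 3 without a filter, where more dim miRNAs are tested, and as 1, 0 and 0 with sex as a covariate. Median scaling and the filter for detection on all arrays gave 0 in both comparisons of codonopsis. In model vs control 5 lists passed with normexp, 1 with log2 taken per probe and 1 with array weights. In codonopsis vs model 5 passed with normexp, 5 with a trended and robust prior, 1 with the brightest probe, 1 with array weights and 1 without miR-297, miR-466, miR-467 and miR-669 entries. In codonopsis vs control 0 passed with log2 per probe or the 2 groups alone, and the 1 that passed with normexp was higher and not the smooth muscle list.

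For single miRNAs, 0 passed in codonopsis vs control with the 75th percentile over all miRNAs, quantile normalization, normexp, detection on at least 1 array, no filter, female mice, a trended and robust prior, or without miR-297, miR-466, miR-467 and miR-669 entries. In the last, 3 of the 4 were left out and miR-3097-5p no longer passed. The floor lowered to 0.5 times gave 2 and detection on all arrays 1, all among the 4, and array weights gave 37 with the 4 included. Slide row gave 2 and 3 passed with the deposited log2 table, with none of the 4 among them. In codonopsis vs model 2 passed with total signal, 1 with the deposited log2 table, 17 with the 2 groups alone and 37 with array weights, and in model vs control 1 with slide row. For any difference among the groups 6 passed with total signal, 1 with the deposited log2 table, 5 with the brightest probe, 2 with double the floor, 1 for detection on all arrays, 38 with array weights and 1 with slide row. An unadjusted p under 0.05 with a 2-fold change held for 4 (model vs control), 20 (codonopsis vs model), 16 (codonopsis vs control) and 60 (sex). In the sex comparison 254 passed with the 75th percentile over all miRNAs, 149 with quantile normalization, 126 with the deposited log2 table, 16 with median scaling, 4 with total signal, 34 with the brightest probe, 25 with double the floor, 4 and 5 for detection on all and on at least 1 array, 47 without the group term and 1 without miR-297, miR-466, miR-467 and miR-669 entries.

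Scalings and signals turned some named values. In model vs control, quantile normalization gave 0.11 for the let-7 family and 0.12 for miRNAs known to fall in fibrotic lung, under a median of 0.36 over all miRNAs, and in codonopsis vs model the deposited log2 table gave −0.05 for let-7 beside a median of −0.17. In model vs control, the 75th percentile over all miRNAs, quantile normalization and the deposited log2 table gave 0.04, 0.15 and 0.20 for miR-1198-5p, 0.13, 0.16 and 0.23 for miR-1231-5p, 0.13, 0.21 and 0.44 for miR-6997-5p and 0.03, 0.02 and 0.08 for miR-5622-3p, and the first 2 of these gave 0.18 and 0.26 for miR-7222-3p. The deposited log2 table also gave 0.09 for miR-186-5p and 0.15 for miR-700-3p, total signal 0.57 for miR-6997-5p and slide row 0.08 for miR-5622-3p. Normexp, whose offset of 50 shrinks differences of dim miRNAs, gave −0.10 for miR-135a-1-3p, −0.04 for miR-466f-5p and −0.07 for miR-466a-5p, beside a median of −0.07 over all miRNAs. In codonopsis vs model miR-99b-3p was −0.02 with normexp and −0.06 with the deposited log2 table. In codonopsis vs control normexp gave −0.01 for miR-466a-5p, 0.00 for miR-3097-5p, −0.08 for miR-670-5p and −0.17 for miR-99b-3p, beside a median of −0.11 over all miRNAs. For let-7k, male minus female was −0.22 with the 75th percentile over all miRNAs, −0.24 with quantile normalization and −0.05 with the deposited log2 table. The difference of the reversal covariance from its simulated mean, 0.0213, was −0.00113 with the brightest probe, −0.0235 for detection on all arrays and −0.0081 without miR-297, miR-466, miR-467 and miR-669 entries.

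With each array left out in turn, single miRNAs passed in ranges of 0 to 0 in model vs control, 0 to 35 in codonopsis vs model, 0 to 46 in codonopsis vs control, 0 to 36 among the 3 groups and 0 to 112 between sexes (112 without codonopsis 3), and lists in ranges of 0 to 6, 0 to 5 and 0 to 3. The reversal difference ranged from −0.111 (without control 3) to 0.143. Leaving out control 1 lowered the median residual SD from 0.299 to 0.217, which is how it enters comparisons without controls. With female mice the codonopsis group is 1 array, assumed to vary like the other groups. No paired analysis was possible because the labels carry no number that joins mice of different groups. Slide and scan date as blocks were not run, since control is alone on its slide and scan date follows the slide. Many named miRNAs are dim, such as the 4 past the threshold, with mean signals of 14 to 22 on the codonopsis arrays, and low signal limits these most. The 24.024 to 28.432 of the negative control spots is a net signal, a measure unlike this intensity, and sets no level for them.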

Other observations

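The tests of the miR-297, miR-466, miR-467 and miR-669 entries and of the muscle miRNAs were chosen only after the result was seen, while the counts over other splits of the arrays were planned.

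Striated muscle miRNAs set codonopsis 2 apart from its group. The levels of miR-1a-3p were 2.07 on codonopsis 2 and −1.84 and −2.14 on codonopsis 1 and 3, against 0.40 to 1.39 on the other 6 arrays, and miR-133a-3p and miR-133b-3p moved in the same way, at 0.88 and 1.51 against −3.23 to −2.44. Without codonopsis 2, miR-1a-3p, miR-133a-3p, miR-133b-3p and miR-133a-5p passed in limma. The log2 differences of the first 3 were −2.78 to −2.62 from the model and −2.62 to −2.50 from control, while codonopsis 1 and 3 did not detect miR-133a-5p, whose values there stand at the floor, so no difference is given for it. On the same array the erythroid markers miR-451a (5.57), miR-486a-5p (−0.75) and miR-144-3p (0.00) read highest of all 9.

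Markers of multiciliated cells, which line the airways, were lowest on codonopsis 1, where miR-34b-5p read 0.06, miR-34c-5p −0.85 and miR-449a-5p −3.80. On the other arrays miR-34b-5p read 0.86 to 1.89. Among leukocyte markers, miR-142a-3p read 1.25 and 1.66 on controls 2 and 3, against −0.41 to 0.44 on the other 7 arrays, whereas the myeloid and leukocyte list as a whole stood out on control 3 alone, with a median deviation of 1.04 against −0.16 on control 2 and at most 0.15 elsewhere. The neutrophil miRNA miR-223-3p was at 2.45 on control 3 and at 0.11 to 1.20 elsewhere. Neither the multiciliated nor the leukocyte list passed in a comparison.

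The 22 miR-297, miR-466, miR-467 and miR-669 entries other than 3p arms were higher on codonopsis than on model arrays for 21 (median 0.96) and than on control arrays for 19 (median 0.88), but with normexp the second median was 0.10, with 15 higher. The 4 miRNAs that passed in the fit of all arrays were all lower on control 1 than the mean of controls 2 and 3, with −0.13 as the highest difference. A miRNA raised on control 1 could hardly pass above the controls. This therefore cannot decide whether the signal that sets control 1 apart plays a part for them. It stays open for the 22 entries as well, of which 14 were higher on control 1. Sex or slide row cannot be told apart from treatment in full, since codonopsis 3 is the 1 female and row 2 array of its group, although it stood above the model arrays by a median of 0.83 and above each of them for 19 of 22 entries. Without control 1 their residuals correlated with a median r of 0.545 against a 95th percentile of 0.151 in random sets, consistent with probes of near-identical sequence reading one another's targets or with shared transcription, so they may amount to few independent signals, and an effect of the treatment is a hypothesis.

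A candidate explanation for the muscle miRNAs is striated muscle in the tissue piece, such as the heart muscle sleeves of mouse pulmonary veins. Over the 9 arrays their mean followed that of the heart-restricted miR-208a-3p and miR-499-5p with r = 0.649 (permutation p = 0.0638) and rho = 0.6 (permutation p = 0.0982), both 0.0982 after adjustment over these 2, and with r = 0.809 without codonopsis 1 and 3, the farthest from the median. Only codonopsis 2 detected miR-208a-3p, and only codonopsis 2 and model 2 detected miR-499-5p, so the test leaves this open. Sex as the cause is argued against by the difference of 3.95 between codonopsis 2 and codonopsis 1, both male, against an SD of 0.481 among model arrays.

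Other splits of the 6 arrays of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For single miRNAs the real split gave 0 and the highest other 0 in model against control and in codonopsis against model, and since any split reaches 0 this decides nothing. In codonopsis against control the real split gave 4 and the highest other 21, so 2 of 10 splits gave as many. The split with 21 sets control 1 and codonopsis 1 and 2, the male arrays, against the female ones, which points to a structure of the samples by sex or by control 1. Sex as a covariate gave 5, with 3 of the 4 among them. Slide row as a covariate, here the same fit as leaving out codonopsis 3, gave 2, with none of the 4. For lists the real and highest other counts were 3 and 8 in model against control (9 of 10 splits as high), 3 and 6 in codonopsis against model (7 of 10) and 1 and 12 in codonopsis against control (8 of 10), and in each comparison other splits also gave fewer lists than the real one.

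Over all 9 arrays, the test of any group difference and the sex comparison gave 0, which 100 of 100 and 81 of 81 splits reach whatever the values, so these counts say nothing about chance. The highest other counts were 24, which points to a structure other than the groups, and 7. For reversal chance cannot be excluded, since the covariance of −0.0998 was reached by 56 of 100 splits, with −0.653 as the most negative.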
